A study of Mus musculus with 8 samples.

How the data were processed

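The study sequenced cDNA libraries made from total RNA of HSCs sorted from mouse bone marrow, with 4 Nynrin CKO and 4 control libraries. Groups and replicate numbers were taken from the sample labels. Per the labels' protocols, about 3000 HSCs per sample were sorted by flow cytometry, RNA was extracted with Trizol, and 5 ng of cDNA entered each library. A transposase-based kit is named in the series text, which also gives a smaller cell number beside 3000. The markers of the sort gate are not given in the sources used here. How the cDNA was primed and amplified is not given in the sources used here.

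The authors deposited whole-number read counts per gene, 1 column per library and not normalized, per the file headers and the values. The table held 55401 genes with Ensembl mouse identifiers and coordinates, and the genome build was mm10 per the submitters' processing notes. The aligner, the counting program, the strand setting and the handling of reads with several matches are not given in the sources used here. Reads of overlapping or near-identical gene records can therefore fall on either record. The pair of records for Septin2 and the pair for Nnt swapped counts between libraries and were not interpreted. Among the genes named, Cdh23, Sirt3, mt-Atp6, mt-Nd6, Mrps18c, Mrpl18, Mrps7, Etfdh, Prdx5, Prdx2, Bid, Cdc20, Gimap1, Ddit3, Rpl35, Mybbp1a and Plvap share part of their region with another record, on either strand, that holds at least 10% of their own counts.

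Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr, which kept 27573. Libraries were scaled by TMM factors, and a quasi-likelihood F-test with robust estimation compared the groups, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values are scaled by the same factors. Means are given ± SD over 4 libraries. Single values and library measures were compared by two-sided exact permutation over 70 assignments of the 8 libraries, on log2(CPM + 1) for genes, for which the smallest possible p is 0.0286. Total counts ran from 36942835 to 56437299 per library. At that depth a gene at 10 CPM has over 300 counts. Several named genes lie far below that in controls, Ighv5-16 with counts in 1 of 4, so their large fold changes are imprecise.

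Before the data were examined, 42 gene lists were written down, of which 41 were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, with a sex check list left out. Each list with 5 or more tested members entered. The same test with an estimated correlation and fry were alternatives. Camera compares a list with all other genes, so a shared trend such as one on transcript length enters it. KEGG terms were taken from the authors' table and tested with Fisher's exact test among annotated tested genes, for terms of 10 to 300 genes.

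Named genes followed a rule fixed before the data were examined. Nynrin and Ppif were always named. Then came up to 12 genes per direction with the largest log2 fold change among those that passed, lay apart in all 4 against 4 libraries, had a mean of at least 10 CPM in the higher group and had no clone or predicted-gene symbol. For each list described, the 4 passing members with the smallest p were named, or, where none passed, the 2 with the smallest p. A result that this rule would name is not reported here. In all, 563 higher and 130 lower genes met the rule's conditions.

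Alternatives fixed before the data were examined were other scaling factors, other filters on low counts, DESeq2 1.42.0, limma-voom with quality weights, a quasi-likelihood fit without robust estimation, a replicate term, 1 surrogate variable from sva 3.50.0, removal of each library in turn and removal of mitochondrially encoded, ribosomal protein and haemoglobin genes. Chosen after seeing the data were a newer form of the quasi-likelihood fit, sums of the similar Nynrin CKO libraries, terms or subsets for library set and Xist class, and removal of a spline trend on transcript length and GC content per library. The library sets were drawn at 300 CPM of receptor reads and the Xist classes at 100 CPM. Values within library sets for single genes came from a model with 1 mean per group and set, in which control 4, alone in its cell, is assumed to vary like the others. Transcript length and GC content were those of each gene's longest transcript in the GENCODE annotation of the same build, and expressed genes were those with a mean of at least 1 CPM. Matched random lists took, for each of the 156 mitochondrial genes, 1 of the 100 genes nearest in transcript length and mean expression, drawn 10000 times, and the draws within library sets were chosen after seeing the data.

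The fit was tested on simulated counts for the 27573 tested genes with the means and library sizes of this comparison. It recovered 67 of 100 genes changed 4-fold and 19 of 100 changed 2-fold, with 5 calls among unchanged genes. The simulated libraries were independent of each other. The simulation therefore does not measure false calls where Nynrin CKO libraries resemble each other in pairs.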

Results

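RNA was sequenced from haematopoietic stem cells (HSCs), the marrow cells that renew themselves and give rise to all blood lineages. The cells were sorted from bone marrow of C57BL/6 mice aged 8 weeks, about 3000 cells per sample. There were 2 groups of 4 libraries. In the Nynrin CKO group, floxed Nynrin was deleted by Cre recombinase under the Tie2 promoter, which is active in endothelium and in blood cells. The controls carried the floxed alleles without Cre and are labelled wild type. The series title ties Nynrin to HSC function and to opening of the mitochondrial permeability transition pore. The comparison therefore asks how the HSC transcriptome differs where Nynrin is deleted. Cre was present in the Nynrin CKO group only, so effects of Cre itself cannot be told apart from those of Nynrin loss. Nor can deletion in HSCs be told apart from deletion in endothelium. Deposited gene counts summed to 36942835 to 38101977 in controls 1 to 3 and 50260720 in control 4, and to 43998525 to 56437299 in Nynrin CKO. The labels do not say that each library came from a separate mouse, so p-values measure the spread between these libraries, which may be partly technical.

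The libraries fell into sets that the groups do not explain. Control 4 and Nynrin CKO 3 and 4 had counts on 28914 to 31344 genes, and the other 5 libraries on 40240 to 44562. Summed counts on 1766 olfactory and vomeronasal receptor genes, which blood cells are not known to use, were 134 to 213 CPM (counts scaled to library size) in those 3 libraries and 854 to 1601 CPM in the other 5. These are called below the set with few receptor reads and the set with more. Xist, transcribed from the inactive X of females, had 177719 and 224087 counts in controls 3 and 4 and 245 to 471 in the other 6 libraries, and Y-linked genes showed the reverse. Nynrin CKO 1 and 2 resembled each other closely, with a biological coefficient of variation of 0.159, as did 3 and 4 with 0.150. It was 0.215 to 0.292 between controls and 0.383 to 0.393 between these Nynrin CKO pairs. Mitochondrially encoded genes took 6.48% ± 0.67 of counts in controls and 8.27% ± 1.86 in Nynrin CKO (SD, n = 4 each), a difference within the spread (two-sided exact permutation p = 0.171, adjusted p = 0.228 over 4 library measures).

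Nynrin itself was lower in every Nynrin CKO library. The gene (ENSMUSG00000075592) lies on chromosome 14 from 55854010 to 55874736 on the plus strand in mm10. Its level was 37.3 ± 8.56 CPM in controls and 10.4 ± 2.49 CPM in Nynrin CKO (SD, n = 4 each), so 27.8% of the control level remained. Raw counts ran from 1280 to 1996 in controls and from 342 to 598 in Nynrin CKO. The log2 fold change was -1.85 with a standard error of 0.22 (edgeR quasi-likelihood adjusted p = 0.0345; two-sided exact permutation p = 0.0286, the smallest that 4 against 4 can give). It was -1.66 within the set with more receptor reads and -1.89 within the set with few. Gene-level counts include any reads from exons outside the deleted part. The adjusted p was 0.0545 to 0.123 without control 1, without control 2 or without any single Nynrin CKO library.

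Ppif, which encodes cyclophilin D, the matrix protein that sensitises the permeability transition pore to calcium, was higher in all 4 Nynrin CKO libraries. The gene (ENSMUSG00000021868) lies on chromosome 14 from 25694154 to 25700468. It measured 129 ± 8.42 CPM in controls and 217 ± 17.4 CPM in Nynrin CKO (SD, n = 4 each), a ratio of 1.68. The log2 fold change was 0.75 with a standard error of 0.10 (edgeR adjusted p = 0.0345; exact permutation p = 0.0286), and it was 0.64 and 0.89 within the sets with more and few receptor reads. Among 24 tested genes reported as parts or regulators of the pore, 6 rose and none fell, and 12 passed when adjusted over the list alone. Besides Ppif these included Sirt3, a mitochondrial deacetylase (log2 fold change 0.76), Tspo, an outer-membrane translocator protein (0.91), and Atpif1, the inhibitor of ATP synthase (0.68). The list's median was 0.43 (camera adjusted p = 3.94e-09 with a preset correlation, adjusted p = 0.200 with an estimated correlation). That median was 0.31 and 0.33 within the sets with more and few receptor reads. It was 0.28 after removal of a trend on transcript length and GC content. The Ppif adjusted p was 0.0545 to 0.136 when any library but control 4 was left out, and 0.0546 and 0.0581 with RLE factors and total counts. Among 20 genes of mitochondrial calcium handling, Atp2a3, a calcium pump of the endoplasmic reticulum, fell from 761 ± 188 to 422 ± 17.7 CPM (log2 fold change -0.85), and the list as a whole did not pass (camera adjusted p = 0.235).

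**Figure D1:**
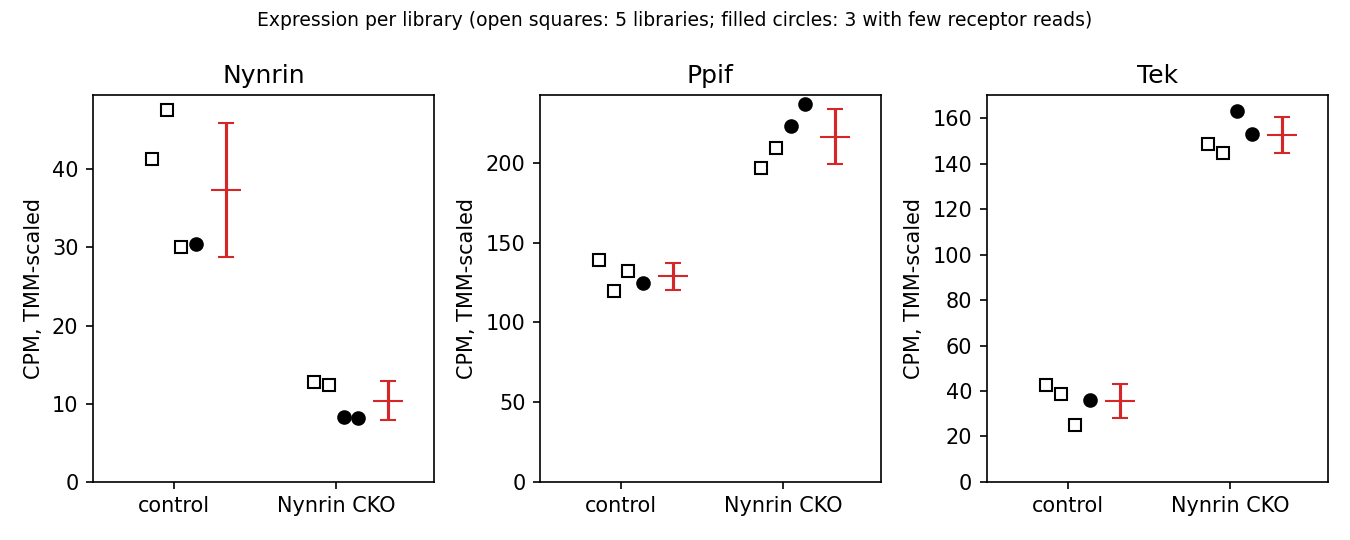
Nynrin, Ppif and Tek in each library, in TMM-scaled CPM on axes from 0, for 4 controls and 4 Nynrin CKO. Filled circles are the 3 libraries with few receptor reads, open squares the other 5, and red bars the mean ± SD. Nynrin lies between 8.22 and 12.7 CPM in Nynrin CKO and at 30.1 CPM or more in controls, and the groups lie apart for Ppif and Tek as well.

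Over all genes, far more passed the test upward than downward. Of 27573 tested, 611 were higher in Nynrin CKO and 162 lower (edgeR, adjusted p threshold 0.05), and every call lay apart in all 4 against 4 libraries. In all, 3956 of the 27573 tested genes lay apart in this way. Chance alone gives a share of 2.86% if the 8 libraries are independent. With Nynrin CKO libraries that resemble each other in pairs the chance share is higher, so no excess over chance can be read from this number. At an unadjusted p under 0.05 the counts were 3629 and 1593. The direction depended on scaling: 79.0% of calls were higher with TMM, 47.3% with upper-quartile factors, 37.1% with RLE factors (13 higher, 22 lower) and 15.6% with total counts (59 and 318). The median log2 fold change of all tested genes was -0.09 with TMM, -0.20 with upper-quartile factors and -0.34 with total counts. Without any of controls 1 to 3 or of the 4 Nynrin CKO libraries, 1 to 6 genes were called higher and 0 to 4 lower, not all of them among the 773, against 1129 and 243 without control 4. When Nynrin CKO 1 and 2 were summed, and 3 and 4 likewise, edgeR called 0 genes, with 3597 at an unadjusted p under 0.05. In a separate fit of the set with more receptor reads 1209 genes were higher and 747 lower. That fit counts the closely similar Nynrin CKO 1 and 2 as separate replicates, so its spread may be too small. The set with few has 1 control, so no count of calls is given for it. With the Xist class as a term 4 were higher and 6 lower.

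Log2 fold changes also followed transcript length. Expressed genes were divided into 5 equal groups by length. In the group with the shortest transcripts, up to 1665 bases, the median log2 fold change was 0.38, and 248 genes were higher and 3 lower. In the group with the longest, from 5063 bases, it was -0.17, with 18 higher and 77 lower. A trend of the same sign was seen between controls, where control 4 over controls 1 to 3 had medians of 0.14 in the shortest group and -0.11 in the longest. After removal of a length and GC trend per library, 2 genes passed in each direction, with 3522 at an unadjusted p under 0.05.

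**Figure D2:**
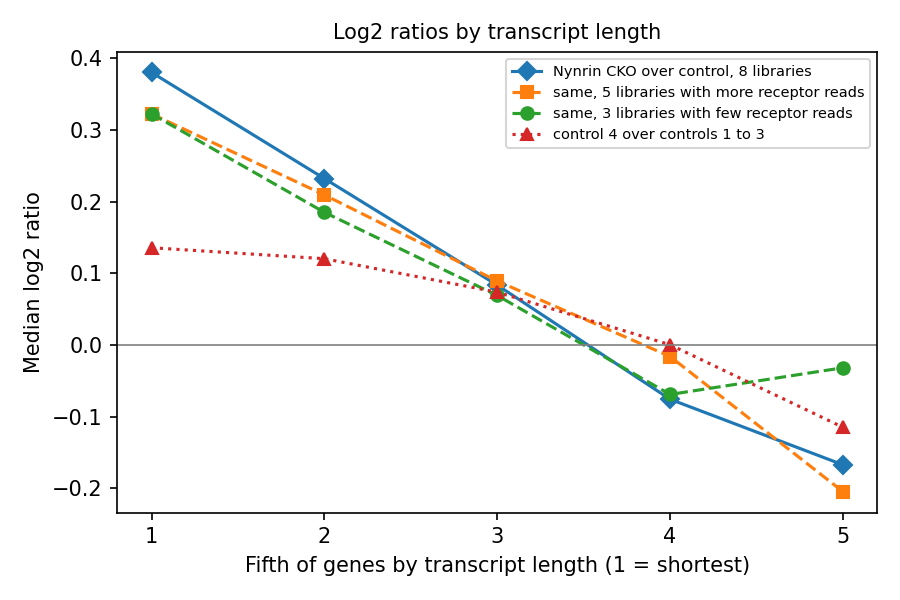
Median log2 ratio, on the vertical axis, over 5 equal groups of expressed genes ordered by transcript length, on the horizontal axis. Lines show Nynrin CKO over control in all 8 libraries, in the 5 with more receptor reads and in the 3 with few, and control 4 over controls 1 to 3. The ratio over all 8 libraries falls from 0.38 in the shortest group to -0.17 in the longest.

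Genes of mitochondrial respiration and translation were higher together. All 36 nuclear-encoded subunits of complex I, which takes electrons from NADH, had positive log2 fold changes, with a median of 0.54. Of these 15 rose, and 32 passed when adjusted over the list alone. Ndufb7 (0.64), Ndufs8 (0.61), Ndufa7 (0.65) and Ndufb10 (0.61) had the smallest p. The camera adjusted p was 2.92e-23 with the preset correlation, and the adjusted p = 0.200 with an estimated correlation. For the 25 subunits of complexes II to IV, 6 rose, among them Sdhb (0.81), Cox5a (0.76), Uqcr10 (0.66) and Cox6b1 (0.58), and 18 passed adjusted over the list alone (median 0.47, camera adjusted p = 1.90e-15, adjusted p = 0.200 with an estimated correlation). For ATP synthase, 2 of 17 rose, Atpif1 and Atp5o (0.62), and 14 passed adjusted over the list alone (median 0.51, camera adjusted p = 9.99e-11, adjusted p = 0.210 with an estimated correlation). Of 78 proteins of the mitochondrial ribosome, 25 rose and 60 passed adjusted over the list alone, with a median of 0.49 (camera adjusted p = 6.33e-28, adjusted p = 0.200 with an estimated correlation). Mrps18c (0.76), Mrpl18 (0.74), Mrps7 (0.61) and Mrps14 (0.78) led it, and the first 3 share their region with another counted gene.

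The 13 protein-coding genes of the mitochondrial genome all had positive log2 fold changes with a median of 0.89. Of these 7 rose, including mt-Nd2 (0.91), mt-Atp6 (1.01), mt-Nd6 (0.91) and mt-Nd1 (0.86), and 13 passed adjusted over the list alone (camera adjusted p = 5.16e-18, adjusted p = 0.200 with an estimated correlation). The median was 0.61 within the set with more receptor reads and 1.02 within the set with few. The share of unscaled counts on all mitochondrially encoded records, not only the protein-coding ones, was 9.86% and 9.90% in Nynrin CKO 3 and 4. It was 6.56% and 6.78% in Nynrin CKO 1 and 2, within the control range of 5.98% to 7.44%. The protein-coding genes named here were nonetheless above every control in Nynrin CKO 1 and 2. For mt-Nd1 these were at 4124 and 4120 CPM, and controls at 2223 to 2744 CPM. mt-Atp6 and mt-Nd6 overlap or adjoin other counted mitochondrial genes. Across the 156 nuclear-encoded members of the 4 respiration and translation lists, the median was 0.50 and 154 were positive. It was 0.49 within the set with more receptor reads, 0.31 within the set with few, 0.25 after removal of the length and GC trend and 0.23 with total counts. Random lists matched on transcript length and expression had a median of 0.41, with 95% between 0.36 and 0.45. Within the set with few receptor reads they had a median of 0.28, with 95% between 0.21 and 0.34, which takes in the 0.31 observed there.

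Other mitochondrial and metabolic lists followed in part. Of 19 genes of fatty acid oxidation 5 rose, including the carnitine carrier Slc25a20 (0.52), Etfa (0.68), Acadl (0.69) and Etfdh (0.54), and 13 passed adjusted over the list alone (median 0.44, camera adjusted p = 1.45e-08, adjusted p = 0.200 with an estimated correlation). Of 23 genes of the tricarboxylic acid cycle 4 rose, the malate dehydrogenase Mdh2 (0.79), Sdhb and the pyruvate carriers Mpc1 (0.90) and Mpc2 (0.47), and 10 passed adjusted over the list alone (median 0.36, camera adjusted p = 1.60e-06, adjusted p = 0.283 with an estimated correlation). Of 28 antioxidant genes 2 rose, Prdx5 (0.60) and Prdx2 (0.57), and 7 passed adjusted over the list alone (camera adjusted p = 1.71e-04, adjusted p = 0.257 with an estimated correlation). Glycolysis did not pass: none of 21 genes reached the threshold (median 0.13, camera adjusted p = 0.140), with Ldha at 0.39 (adjusted p = 0.138) and Eno1 at 0.495 (adjusted p = 0.160).

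**Figure D3:**
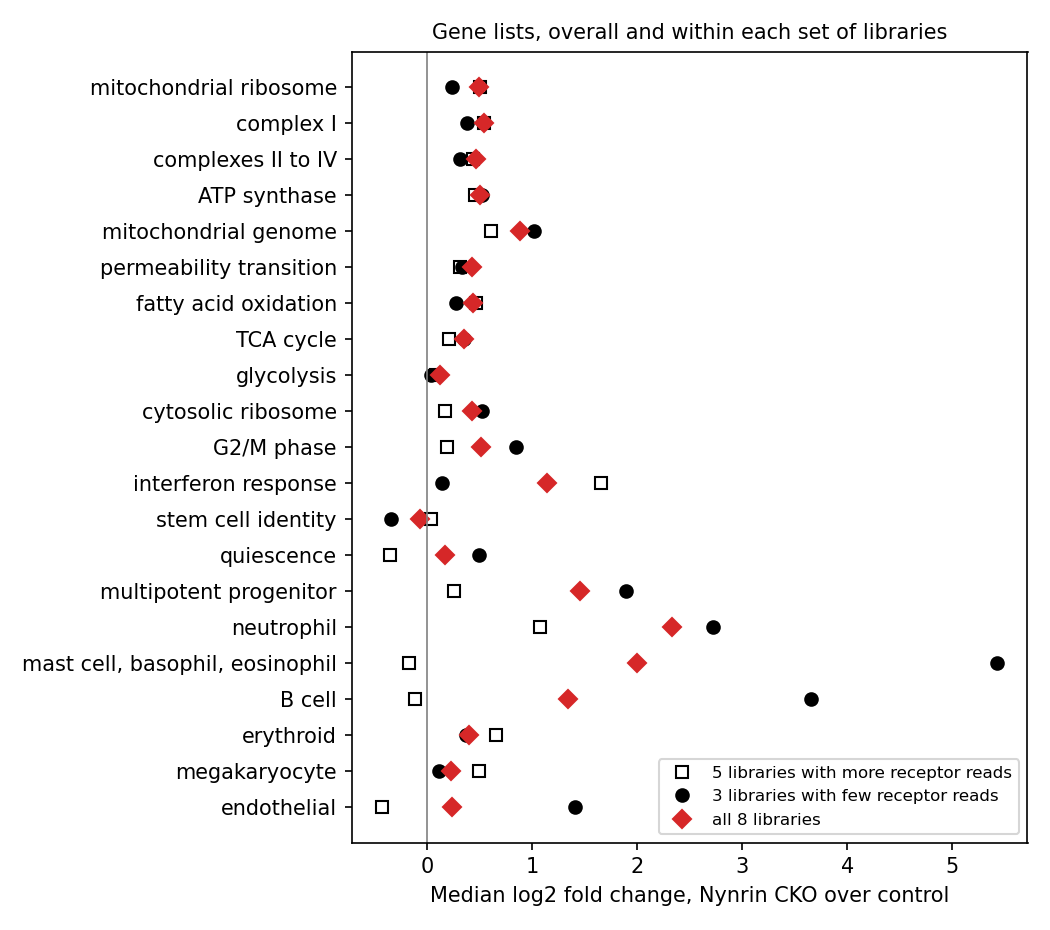
Median log2 fold change of Nynrin CKO over control, on the horizontal axis, for 21 gene lists on the vertical axis. Red diamonds are all 8 libraries, open squares the 5 with more receptor reads and filled circles the 3 with few. Respiration lists lie above 0 in both sets, while the mast cell list lies at -0.17 in the set with more receptor reads and at 5.42 in the set with few.

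Among stem cell genes, Tek had the largest rise. Tek, also called Tie2, is the angiopoietin receptor that holds HSCs in the marrow niche, and its promoter drives Cre in this line. The gene lies on chromosome 4 from 94739289 to 94874976. It rose from 35.5 ± 7.43 to 153 ± 7.93 CPM (SD, n = 4 each), 4.29 times the control level, with a log2 fold change of 2.10 and a standard error of 0.16. Its edgeR adjusted p of 0.00620 was the smallest of all genes (exact permutation p = 0.0286), and its log2 fold change was 2.05 and 2.14 within the sets with more and few receptor reads. Counts at gene level cannot separate Tek transcripts from any Tek sequence carried by the Cre transgene. Among 34 HSC identity genes, only Tek and the GTPase gene Gimap1 (0.52) rose and none fell (median -0.06, camera adjusted p = 0.741). Tek was also the single member to rise among 30 genes of quiescence (median 0.17, camera adjusted p = 0.125). Among 26 adhesion and niche receptors Tek and Cxcr2 (1.23) rose, with a median of -0.06, a mean of 0.13 and an upward test direction (camera adjusted p = 0.168). The Tek adjusted p was 0.191 with the Nynrin CKO pairs summed and 0.103 in the 6 libraries with low Xist.

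Several genes with large log2 fold changes upward had higher CPM in Nynrin CKO 3 and 4 than in 1 and 2. Ctsg, a serine protease of granulocyte precursors, was at 12.1 and 12.7 CPM in Nynrin CKO 1 and 2, at 218 and 231 CPM in 3 and 4, and at 0.80 to 5.02 CPM in controls (log2 fold change 5.28, adjusted p = 0.0478). Ms4a3 (3.83), the monocyte antigen gene Ly6c2 (3.64), Anxa3 (3.23), the histamine-forming enzyme Hdc (2.95), the mast cell protease Cpa3 (2.85) and Chil3 (2.59) rose as well, as did the antibody segment Ighv5-16 (9.09), which reached 24.6 and 26.2 CPM in Nynrin CKO 3 and 4. Whether the effect of genotype differed between the library sets cannot be decided, because the set with few receptor reads has 1 control. Log2 fold changes within the sets with more and few receptor reads were 1.639 and 6.067 for Ms4a3. They were 1.229 and 5.903 for Ly6c2, 1.555 and 4.317 for Anxa3 and 1.293 and 3.51 for Hdc. For Ighv5-16 they were 6.066 and 13.157, for Ctsg 1.865 and 6.792 and for Chil3 1.597 and 3.536. For Cpa3 they were 2.037 and 3.053 and for Cxcr2 1.131 and 1.575. Of 20 neutrophil genes, 4 rose (Chil3, Ms4a3, Ctsg and Cxcr2) and 13 passed adjusted over the list alone, with a median of 2.33 (camera adjusted p = 6.69e-12, adjusted p = 0.210 with an estimated correlation). The median was 1.08 within the set with more receptor reads and 2.72 within the set with few. Of 18 mast cell, basophil and eosinophil genes, Cpa3 and Hdc rose and 7 passed adjusted over the list alone (median 2.003, camera adjusted p = 2.06e-07, adjusted p = 0.257 with an estimated correlation). That median was -0.17 within the set with more receptor reads. Of 23 multipotent progenitor genes, Ms4a3 and Ctsg rose and 15 passed adjusted over the list alone (median 1.46, camera adjusted p = 1.75e-10, adjusted p = 0.283 with an estimated correlation), with medians of 0.26 and 1.90 within the sets with more and few receptor reads.

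Markers of other lineages were mixed. Of 19 erythroid genes, the carbonic anhydrases Car2 (0.76) and Car1 (1.34) and the erythroid transcription factor Klf1 (1.19) rose (median 0.41, camera adjusted p = 1.92e-04, adjusted p = 0.283 with an estimated correlation), 3 of 19 also when adjusted over the list alone. The cytotoxic granule gene Nkg7 (1.72) was the 1 of 22 T and NK cell genes to rise, over all genes and adjusted over the list alone (camera adjusted p = 6.84e-05, adjusted p = 0.200 with an estimated correlation). No B cell gene of 21 passed over all genes and 6 did adjusted over the list alone (median 1.34, camera adjusted p = 1.85e-05, adjusted p = 0.283 with an estimated correlation), and the median was -0.12 within the set with more receptor reads. Jchain was at 3.07 (adjusted p = 0.0632) and Cd22 at 1.66 (adjusted p = 0.0655). No monocyte or macrophage gene of 24 passed over all genes and 14 did adjusted over the list alone (median 1.08, camera adjusted p = 1.73e-08, adjusted p = 0.200 with an estimated correlation), with C1qb at 1.19 (adjusted p = 0.0503) and C1qa at 1.14 (adjusted p = 0.0520). Within the sets with more and few receptor reads the monocyte and macrophage medians were 0.40 and 1.14, those of T and NK cell genes 0.53 and 2.03 and those of erythroid genes 0.66 and 0.37. Endothelial (median 0.24, camera adjusted p = 0.167), stromal (0.43, 0.154) and megakaryocyte lists (0.23, 0.178) did not pass. The endothelial median was -0.42 within the set with more receptor reads and 1.41 within the set with few.

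Interferon-inducible genes were higher in Nynrin CKO, several of them most of all in libraries 1 and 2. Ifi204, a DNA sensor of the interferon-inducible p200 family, was at 41.1 and 42.9 CPM there and at 7.01 and 6.97 CPM in Nynrin CKO 3 and 4. In controls Ifi204 was at 1.95 to 3.79 CPM (log2 fold change 3.07, edgeR adjusted p = 0.0464). Its relatives Ifi209 (2.61) and Ifi206 (2.37) and the membrane protein gene Ms4a4c (3.21) rose too. Ifi209 reached a like level of 13.6 to 15.5 CPM in all 4 Nynrin CKO libraries. Within the sets with more and few receptor reads, the latter with 1 control, Ifi204 was at 3.93 and 1.03 and Ifi209 at 2.84 and 2.11. Ifi206 was at 3.02 and 1.21 and Ms4a4c at 3.85 and 2.06. All 38 listed interferon-stimulated genes had positive log2 fold changes with a median of 1.14. Psmb8, an immunoproteasome subunit (0.85), was the 1 that passed over all genes, and 24 did adjusted over the list alone (camera adjusted p = 3.16e-14, adjusted p = 0.283 with an estimated correlation). The median was 1.66 within the set with more receptor reads and 0.15 within the set with few. Of 28 NF-kB and inflammatory genes, the chemokine Ccl5 (2.68) and the NF-kB inhibitor Nfkbia (1.06) rose and 8 passed adjusted over the list alone (median 0.37, camera adjusted p = 2.03e-04, adjusted p = 0.200 with an estimated correlation).

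Cell cycle and death genes rose in small numbers. Of 32 genes of G2 and mitosis, Ccnb2 (1.07), Nuf2 (0.62) and Cdc20 (0.83) rose and 18 passed adjusted over the list alone (median 0.52, camera adjusted p = 3.00e-11, adjusted p = 0.257 with an estimated correlation). The median was 0.19 and 0.85 within the sets with more and few receptor reads. Of 30 S phase genes, Ccne1 (0.70), Rrm2 (0.76) and Rfc2 (0.67) rose, and 4 rose and 1 fell adjusted over the list alone (median 0.24, camera adjusted p = 8.93e-04, adjusted p = 0.436 with an estimated correlation). With total counts that median was -0.06, where the median of all tested genes was -0.34. Of 29 apoptosis genes, Casp8 (0.76), Bid (0.76) and Bax (0.56), which act in sequence from death receptors to the mitochondrial outer membrane, rose, and 7 passed adjusted over the list alone (median 0.28, camera adjusted p = 0.00259, adjusted p = 0.200 with an estimated correlation). With total counts the median was -0.0024, again above that of all tested genes. Bax was also the single p53 target of 30 to rise (camera adjusted p = 0.154), and Parp2 (0.63) the single DNA repair gene of 30 (camera adjusted p = 0.235).

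Genes that were lower formed no listed group: 0 lists passed downward. Among genes that met the naming rule, the largest log2 fold changes downward after Nynrin were those of Cdh23 (-1.66), the serotonin receptor Htr2a (-1.43), Manea (-1.32) and Sipa1l3 (-1.30). Next came Prkaa2, a catalytic subunit of AMP-activated protein kinase (-1.24), the growth-linked zinc finger gene Plag1 (-1.20) and the imprinted growth factor adaptor Grb10 (-1.19). B3glct (-1.18), Zdhhc23 (-1.16), Fastkd3, which encodes a mitochondrial RNA-binding protein (-1.12), and Mpdz (-1.09) followed. The edgeR adjusted p of these lower genes ranged from 0.0345 to 0.0458. Cdh23 shares its region with Vsir. All of them were lower within both library sets, from -1.55 to -0.80 with more receptor reads and from -1.76 to -0.64 with few. Manea was at -0.956 and -1.733 within these sets, but 1 control in the set with few cannot settle whether its effect differs. The endoplasmic reticulum stress sensor Ern1 fell from 46.9 ± 6.81 to 25.4 ± 1.53 CPM (log2 fold change -0.88, adjusted p = 0.0345), while the chaperone genes Dnajb11 (0.53), Sdf2l1 (0.59) and Pdia3 (0.71) of the same list of 28 rose. Adjusted over the list alone 8 rose and 1 fell (median 0.32, camera adjusted p = 2.03e-04, adjusted p = 0.283 with an estimated correlation).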

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

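The tests of library sets for the mitochondrial and the granulocyte genes, of length within library sets, of endothelial cells, long-term stem cells and the transgene for Tek, and of a lower share of stem cells were chosen only after the result was seen. In 224 groups of 4 values, 13 held a library far from the other 3, most of them among controls. Chance gives about 11.2 if the libraries vary independently. The similar Nynrin CKO pairs leave little room for 1 library apart from 3, so the 2 numbers cannot be compared directly. Control 4 stood apart in total count (50.26 M against 36.94 M to 38.1 M) and in genes detected (31340 against 42560 to 44560). It was also the high control for Mrps7 (66.5 CPM against 56.1 to 57.3), Prdx2 (267 against 197 to 207) and Dnajb11 (72.2 against 58.4 to 59.9). Control 1 was high for Ccnb2 (89.7 against 59.8 to 64.6) and Nuf2 (36.6 against 28.2 to 29.2). Control 2 was low for Ccl5 (0.476 against 1.36 to 1.53), Car2 (965 against 1237 to 1281) and Psmb8 (202 against 305 to 312). Control 3 held the only control counts on Ighv5-16, at 0.0940 CPM. Nynrin CKO 4 was high for Sipa1l3 (31.4 against 23.9 to 24.4) and Nynrin CKO 3 for Cd22 (3.22 against 1.53 to 1.64).

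Of the 35 splits of the 8 libraries into 4 and 4, only the real split, 1 of 35, gave as many as 773 genes, and the highest other gave 1, so chance can be excluded for that count only if the 8 libraries are independent. At an unadjusted p under 0.05 the real split gave 5222 genes and the highest other 4359, so the gap at the adjusted threshold is far wider than that in the evidence beneath it. Only 7 splits keep Nynrin CKO 1 with 2 and 3 with 4, too few for a share under 0.05, so if each of these pairs is 1 source the splits decide nothing. For gene lists, 12 of the 35 splits gave as many as 29 and the highest other gave 36, so chance cannot be excluded for the number of lists. The split of control 1, control 4 and Nynrin CKO 3 and 4 from the rest, which keeps the 3 libraries with few receptor reads together, gave 36.

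The rise of 156 nuclear-encoded mitochondrial genes had a median log2 fold change of 0.50 (standard error 0.02 over genes, not libraries). Transcript length and expression together may carry most of it, since random lists matched on both had a median of 0.41. Lists matched on expression alone had a median of 0.19. The observed median lay above 0.45, the upper end of the central 95% of lists matched on both. Those draws treat genes as independent, so they cannot decide whether length is the whole cause. Within the set with more receptor reads the median was 0.49 against an upper end of 0.42. Within the set with few, which has 1 control, it was 0.31 against 0.34. No rise beyond lists matched on length and expression was seen there. A difference between library sets as the whole cause is argued against within the set with more receptor reads, where the lowest Nynrin CKO library lay 0.38 above the highest control and the controls spanned 0.24, and sex of the animals by a median of 0.59 with the same gap in the 6 libraries with low Xist. What stays open is length as the whole cause, a biological effect of Nynrin loss or of Cre on any part beyond it, and any source shared by the similar Nynrin CKO libraries.

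The rise of Tek by 117 CPM could come from endothelial cells in the gate, but the other 23 endothelial genes rose by a median of 1.47 CPM (standard error 3.35), with Egfl7 (36.2 CPM) and Stab2 (31.4 CPM, log2 fold change 1.74) highest and Pecam1 at 10.5 CPM, so a few endothelial cells are not excluded but do not account for 117 CPM. A larger share of long-term stem cells as the source of the whole rise is argued against by the other 33 HSC identity genes. Their median log2 fold change was -0.07 (standard error 0.10 over genes), which does not exclude a smaller shift within the gate. Tek transcribed from the Tie2-Cre transgene cannot be told apart from the endogenous gene at its 4.29-fold level, because gene counts hold no position within Tek. A response of HSCs to Nynrin loss or to Cre itself stays open beside it.

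The rise of 38 granulocyte and mast cell genes had a median log2 fold change of 2.19. A difference between library sets stays open: Nynrin CKO 3 and 4 lay above control 4 by a median of 3.33, but that is 1 control, and within the set with more receptor reads the lowest Nynrin CKO library lay 0.17 above the highest control while the controls spanned 0.74. A lower share of stem cells with all other types raised alike stays open: the median lay above those of endothelial and stromal genes by 1.96 and 1.77 (standard errors 0.38 and 0.39), but within the set with few receptor reads by 1.92 and 2.84 with standard errors of 1.02 and 0.97. For mature neutrophils in the gate, their abundant genes such as S100a8 and Ngp would rise at least as much as granule genes such as Mpo and Elane. The mature genes rose less, with a difference of medians of -2.87 and a standard error of 1.12. The kinds overlapped: 8 mature genes ran from 0.30 for Lcn2 to 2.69 for Retnlg, and 5 granule genes from 0.70 for Prtn3 to 5.28 for Ctsg. S100a8, Ngp, Mpo and Elane did not pass singly (edgeR adjusted p = 0.0985, 0.277, 0.052 and 0.0625). The direction of the medians is against mature neutrophils, but the difference falls short of the 3 standard errors set beforehand, so they stay open. Mpo reached 2830 and 2820 CPM in Nynrin CKO 3 and 4 and S100a8 168 and 170 CPM, so more progenitors in the sort or a change of the HSCs themselves may also contribute, which was not tested.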

How the results depend on the processing

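The length correction, the sums, the terms and subsets for library set and Xist class, and the newer quasi-likelihood fit were chosen after seeing the data. Unless a reason is given, the cause was not tested. Genes higher in Nynrin CKO, 611 as reported, numbered 13 with RLE factors, 59 with total counts, 225 with upper-quartile factors, 33 with no filter (more genes tested), 25 without mitochondrially encoded, ribosomal protein and haemoglobin genes, 1586 with DESeq2 and 1649 with limma-voom. They numbered 0 with the Nynrin CKO libraries summed in pairs (fewer samples), 1221 with library set as a term, 4 with Xist class, 247 with both, 1209 within the set with more receptor reads, 1847 within the set with few, 0 in the 6 libraries with low Xist, 2 after length and GC removal, 1 at an adjusted p under 0.01 and 82 at 2-fold or more. Genes lower, 162 as reported, numbered in the same order 22, 318, 251, 16, 81, 883, 504, 0, 408, 6, 147, 747, 0, 2, 0 and 47, with 824 under the filter of 5 CPM and 290 with the newer quasi-likelihood fit. Without 1 library, 1 to 1129 were higher and 0 to 243 lower, and the counts over 6 and 4 came from the removal of control 4 alone. The settings with 0 calls had 3597 (sums), 4471 (low Xist) and 5144 (replicate block) genes at an unadjusted p under 0.05.

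Whether replicate numbers pair the samples was not settled. Correlations of same-numbered deviations were 0.15, 0.12, -0.13 and 0.28. Most samples correlated best with their own number in the other group, some by small margins. The exceptions were the samples of the pair at -0.13, which lie in different library sets. Correlations were positive within a library set and negative between sets, so they cannot decide whether the numbers mark pairs. With the replicate block 0 genes were higher and 0 lower, 29 lists were higher, and the log2 fold changes of Nynrin and Ppif were -1.85 (adjusted p = 0.0502) and 0.75 (adjusted p = 0.0691).

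Lists higher, 29 as reported, numbered 15 under the filter of 5 CPM, 0 with an estimated correlation and 15 with fry, and 28 to 36 without 1 library. Lists lower, 0 as reported, numbered 1 with a surrogate variable, 1 with both terms, 2 within the set with more receptor reads, and 0 to 1 without 1 library. Nynrin was lower in every setting. It missed the threshold at -1.82 with pairs summed (adjusted p = 0.237) and -2.09 with low Xist (adjusted p = 0.103), and ranged from -2.004 to -1.70 without 1 library. Ppif was higher in every setting, and missed the threshold at 0.70 with RLE factors, 0.47 with total counts, 0.76 with no filter, 0.66 without mitochondrially encoded, ribosomal protein and haemoglobin genes, 0.78 with pairs summed, 0.74 with Xist class, 0.76 with low Xist and 0.82 after length and GC removal (adjusted p = 0.169). It ranged from 0.69 to 0.80 without 1 library. Over its alternatives the Ppif adjusted p ran from 4.32e-06 with DESeq2 to 0.237.

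Among the lists that passed, medians changed sign with total counts for mitochondrial dynamics (-0.075), apoptosis (-0.0024), S phase (-0.0565) and ribosome biogenesis (-0.0001), all above the median of all tested genes there, -0.34, so the lists' sign follows the scaling. Within the set with more receptor reads they did so for senescence (-0.0061), B cell (-0.12) and mast cell genes (-0.17), as they did among lists that had not passed for immediate-early (-0.92), endothelial (-0.42), quiescence (-0.35), p53 target (-0.05) and HSC identity genes (0.04), and with both terms for senescence (-0.23). Plvap (-0.0525) and Ier5 (-0.0184) changed sign within the set with more receptor reads. Of the other named genes 87 had a call, and all 87 lost it with pairs summed, 86 after length and GC removal and 84 with Xist class, without change of sign. The labels do not give the number of independent animals.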

Other observations

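Of 86 cytosolic ribosomal proteins 85 had positive log2 fold changes, with a median of 0.43, while 1 passed, Rpl35 (0.998), and 0 adjusted over the list alone (camera adjusted p = 4.63e-18, adjusted p = 0.286 with an estimated correlation). Among 30 ribosome biogenesis genes Utp20 (-0.53) and Mybbp1a (-0.48) fell, while the list's median was 0.27 and 6 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.00407, adjusted p = 0.465 with an estimated correlation). Among 33 autophagy and lysosome genes Atg12 (0.66), Npc2 (0.85) and Becn1 (0.54) rose, and 7 passed adjusted over the list alone (median 0.31, camera adjusted p = 6.05e-05, adjusted p = 0.283 with an estimated correlation). Among 21 mitochondrial stress genes Ddit3 rose (0.72), and 4 passed adjusted over the list alone (camera adjusted p = 1.71e-04, adjusted p = 0.200 with an estimated correlation), and among 20 genes of mitochondrial dynamics the fission adaptor Mief1 fell (-0.67), and 7 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.0434, adjusted p = 0.327 with an estimated correlation). No member of 25 Myc-linked metabolic genes passed, with 8 higher and 2 lower adjusted over the list alone, and Max at 0.68 and Cad at -0.74 (camera adjusted p = 2.03e-04, adjusted p = 0.371 with an estimated correlation). In the senescence list Ccl5 rose, 1 of 22 (camera adjusted p = 0.00418, adjusted p = 0.257 with an estimated correlation). Cholesterol synthesis, with Nsdhl up (0.68; camera adjusted p = 0.176), and immediate-early genes, with Atf3 at 0.94 and Ier5 at 0.85 (camera adjusted p = 0.177), did not pass.

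Among 308 KEGG terms, 14 were enriched among higher genes and 0 among lower. Oxidative phosphorylation held 34 called genes of 126 (Fisher adjusted p = 5.30e-18), and the proteasome 20 of 45 where 1.70 were expected (adjusted p = 3.77e-15). The spliceosome held 15 of 130 (adjusted p = 0.00274). Members of these complexes were not matched for transcript length.

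A hypothesis was that alleles flanking the floxed locus and carried with it account for calls near Nynrin, and its test was fixed before the result was seen. The controls are described as carrying the floxed alleles too, though labelled wild type. Flanking alleles would then be shared by both groups, so this test can say little about them. Within 10 Mb of Nynrin 14 of 378 tested genes were called, 3.70% against 2.79% elsewhere (one-sided Fisher's exact p = 0.177). The ratio of shares was 1.33 with a 95% interval of 0.791 to 2.23, so neither an excess nor its absence was shown. Ppif lies 30.2 Mb from Nynrin on the same chromosome.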
